A study of Mus musculus with 2 samples.

How the data were processed

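Gene expression was measured in a stem cell line grown as neurospheres from a mouse glioblastoma that had been induced with a transposon. Per the labels, the cells were transduced with a lentivirus carrying either a non-target short hairpin RNA (control) or a hairpin against Stat5b, and stably transduced cells were compared. There was 1 array of each kind, taken from the treatment label, so the comparison had no replicates. Per the labels, total RNA was amplified and labelled with the dye Cy3, and each array carried 1 sample and 1 colour.

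The deposited scanner files hold 1 intensity per spot, read with Agilent Feature Extraction 12.1.0.3 under protocol GE1_1200_Jun14 per the file headers. The processed signal is background-corrected by that software and is not scaled between arrays. The deposited files also hold the error the software gives to each processed signal, the raw median signal and local background, and flags with values 0 or 1 for spots well above background, saturated or of outlying pixels. A table of the authors holds log2 values for the same arrays. Set against the scanner files, each column of the authors' table was log2 of the processed signal minus 1 constant per array, to within 0.001 for 100% of 56294 single-spot probes. The constant was 8.94 for the control array and 8.94 for the knockdown array, which put the 75th percentile of each column at 0. The column medians were -3.83 and -3.83. Scale, centring and direction of the authors' table were thus settled from the values, and it was used as an alternative.

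Each array held 62976 spots, of which 59305 were not controls and made up 56605 probes, 300 of them spotted 10 times. Outlier flags removed 112 non-control spots on the control array and 94 on the knockdown array, and 0 were saturated. A probe's value was the mean of log2 processed signal over its spots, with signals under 1 set to 1, minus the array's 75th percentile over non-control probes. That percentile corresponded to a signal of 493.3 on the control array and 493.7 on the knockdown array. Well above background were 33701 probes (59.5%) on the control array and 33150 (58.6%) on the knockdown array. The negative control spots had a median raw signal of 35.5 and 36. Both arrays lay on 1 slide, so no slide could be set against another. The number of arrays limits the precision.

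Probes were named through the accession the scanner files give and the gene table of assembly GRCm38, used for names and gene order alone because the file headers name build mm9. No coordinates are given for that reason. An accession named 34566 probes, the file's symbol was current for 9190, a synonym was updated for 275, the file's symbol was kept for 2145 and 10429 had no gene name. The named probes covered 26883 genes. A gene's value was the mean over its probes well above background on both arrays. Histone genes and other families of near-identical sequence may share signal between members, so their single values are uncertain.

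With 1 array per group no test was run across genes and no p-value is given for a gene or a list. A gene was counted as higher or lower at a log2 difference, knockdown minus control, of 1 or more in size (2-fold), a rule of size for these 2 arrays. The error printed as ± is the scanner software's own error of the difference and does not cover differences between cultures. It was nearly the same for bright genes with 1 probe, at 0.204 for Jak1, Rrm2 and Gins3, and its median over genes was 0.204. Measured SDs were 0.0558 over replicate spots of 1 probe and 0.310 over different probes of 1 gene. The ± is thus no measured spread, and it falls with the number of probes even where they disagree. A gene whose probes were well above background on 1 array only was given a bound: the bright probe's level over the higher of the lowest signal well above background and the probe's own signal on the other array. The lowest such normalized log2 level was -5.35 on the control array and -5.25 on the knockdown array.

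A total of 40 gene lists were fixed before the data were examined. They covered JAK-STAT components, STAT5 target genes, D and E cyclins and their kinases, DNA replication, mitosis, replication histones, CDK inhibitors, p53 targets, and anti-apoptotic and pro-apoptotic genes. Cell identity lists were neural and glioma stem cell genes and markers of astrocytes, the oligodendrocyte lineage, neurons, microglia and immune cells, and endothelial and mural cells. Signalling lists were interferon-stimulated genes, NF-kB targets, MHC class I antigen presentation, the Notch, Wnt, Hedgehog and TGF-beta and BMP pathways, receptor tyrosine kinases with insulin and PI3K genes, and MAPK feedback genes. The remainder were mesenchymal and invasion genes, hypoxia and glycolysis, the unfolded protein response, cholesterol synthesis, heat shock, oxidative stress, glioma drivers, chromatin silencing, imprinted, axon guidance, reference, ribosomal protein, respiratory chain, Hox and olfactory receptor genes. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean level in 20 bins. A list was said to stand apart under the 2.5th or over the 97.5th percentile, which about 2 of 40 lists would do by chance. Intervals of list medians are 95% order-statistic intervals over genes and describe these arrays.

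Genes were named by a rule also fixed before the data were examined. It took the JAK-STAT genes; the 12 largest rises and 12 largest falls in the upper part of the level range (above the median level), leaving out clone and predicted-gene names and genes whose probes disagreed in sign; up to 4 members of each list that stood apart in its direction and up to 2 in the other; up to 2 members per direction that changed 2-fold in the other lists; and the 5 largest bounds per direction, again without clone or predicted-gene names. Some genes the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

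The steps were tested on simulated data in which the control array was copied with probe noise of SD 0.3 and 200 of 16985 genes were changed. Of the 4-fold changes 100% were counted, of the 3-fold changes 99%, and of the unchanged genes 0.0298%. The noise was the same at all signal levels, and both simulated arrays had the control array's detection flags. Extra noise of dim probes, loss of detection, defects by array row and differences between cultures were absent. The 0.0298% is therefore no error rate for the real counts. A list shifted by 0.5 came out at percentile 100, and 6 of 100 random lists fell outside the limits. Alternatives covered median and quantile scaling, the filter on dim probes, the brightest probe per gene and the authors' table. Added after seeing the data were normexp background correction on the median signal (offset 50), alone and with quantile scaling, the array without its last 64 rows, and RefSeq probes alone. Normexp on the mean signal had been planned, but the files used here carry the median signal, so it was not run as planned. Software was R 4.3.3 with limma 3.58.1 for normexp, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.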

Results

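Transcript levels were measured on 2 single-colour arrays, 1 of mouse glioblastoma stem cells carrying a non-target hairpin and 1 of the same line carrying a hairpin against Stat5b. The comparison asked how lowering Stat5b, a transcription factor activated by cytokine and growth factor receptors, alters gene expression in these cells. There were no replicates, so every difference below describes 2 arrays and could not be set against the spread between cultures. Of the genes on the array, 16354 were measured on both, and their log2 levels correlated at r = 0.982 across genes, which are not independent replicates.

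Stat5b was lower on the knockdown array. Its brighter probe had a processed signal of 1991 on the control array and 498 on the knockdown array, a log2 difference of -2.0 ± 0.20, or 25.0% of control. A dimmer Stat5b probe gave 14.7 and 7.49 and was not well above background on the knockdown array. The close relative Stat5a differed by 0.07 ± 0.14. Stat3, another member of the family, was 1.87-fold higher (0.90 ± 0.15), with its 3 probes between 0.72 and 1.02. Tyk2 was higher by 0.61 ± 0.19. Jak1 differed by 0.38 ± 0.20, Jak2 by 0.25 ± 0.15, Jak3 by 0.35 ± 0.13, Stat2 by 0.06 ± 0.21 and Stat6 by -0.35 ± 0.20. Stat4 was not well above background on either array. The median of the 10 measured JAK-STAT components was 0.30, at percentile 96.5 of random lists. Without the last 64 of the array's 384 rows it was 0.38 at percentile 98.0. Those rows hold the only Stat6 probe, so 1 of the 2 members below 0 was then lost. Over the 10 alternatives the list's median ranged from 0.17 to 0.38 and its percentile from 81.5 to 98.0.

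**Figure D1:**
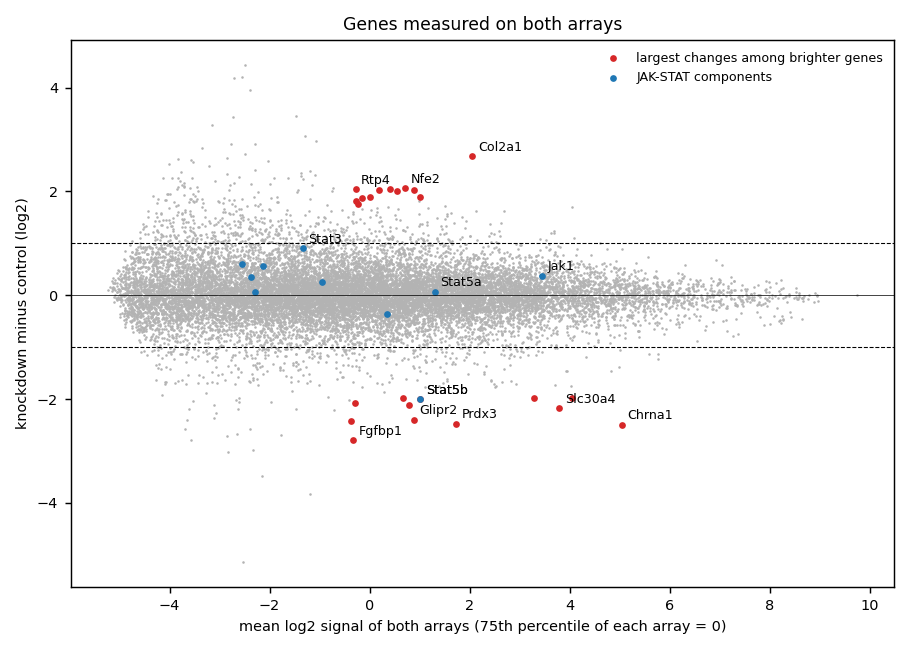
Knockdown minus control log2 difference of each gene measured on both arrays (grey) against its mean log2 signal, with 75th percentiles at 0, dashed lines at 2-fold, JAK-STAT components in blue and the largest changes among brighter genes in red. Stat5b lies at -2.0, Stat5a at 0.07 and Col2a1 at 2.68.

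At least 2-fold higher on the knockdown array were 600 genes (3.67%), and 394 (2.41%) were at least 2-fold lower. Changes of 4-fold or more were counted for 62 genes upward and 33 downward. Large changes were more frequent in the last 64 of the array's 384 rows. Of probes well above background on both arrays, 1.06% differed 4-fold or more there, against 0.36% in the other rows. For 2-fold the shares were 7.57% and 5.43%. Without those rows 525 genes were higher and 321 lower, of 14682 measured. The highest rises among brighter genes were those of Col2a1, the cartilage collagen chain (2.68 ± 0.20), Nfe2 (2.07 ± 0.20), Slc16a4 (2.06 ± 0.20), the interferon-inducible Rtp4 (2.04 ± 0.21), the exporter Abcc3 (2.03 ± 0.20), Pcp4l1 (2.03 ± 0.14) and Cstad (2.01 ± 0.20). Rab19 (1.90), Cysrt1 (1.90), Atp1b2 (1.88), C2cd4b (1.82) and Col5a3 (1.76) followed. The deepest fall among brighter genes was that of Fgfbp1, a carrier of fibroblast growth factors (-2.79 ± 0.15). Next were the acetylcholine receptor subunit Chrna1 (-2.50 ± 0.20) and the mitochondrial peroxiredoxin Prdx3 (-2.47 ± 0.20). Then came Strip2 (-2.43 ± 0.21), Glipr2 (-2.40 ± 0.20) and the zinc transporter Slc30a4 (-2.17 ± 0.20). Hmgb3 (-2.11), Pvr (-2.08), Ptp4a2 (-1.99), Marcks (-1.99) and Purb (-1.99) followed. Prdx3, Purb and Rab19 were each measured by probes in the last 64 of the array's 384 rows alone, where signals present on 1 array gathered. Without the filter on dim probes Cstad and Col5a3 fell short of 2-fold, and a second Col5a3 probe, well above background on the control array alone, was at -0.17.

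Replicate spots of 1 probe differed with an SD of 0.0558 in log2 difference, and different probes of 1 gene with an SD of 0.310. Of 281 counted genes with several measured probes, 157 passed 2-fold with each probe in the same direction and 7 had probes of opposite sign. With normexp background correction, which damps dim probes, 191 genes were higher and 167 lower. Among brighter probes alone the counts were 211 and 229, and without the filter on dim probes 1282 and 1000.

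Genes of cell division were lower on the knockdown array. All 30 measured mitosis genes lay below 0, with a median of -0.65 (interval -0.73 to -0.59) against -0.14 to 0.15 for random lists, at percentile 0. Cyclin A2 (Ccna2) was at -1.16 ± 0.14, the hyaluronan receptor Hmmr at -1.13 ± 0.12, the kinase Aurkb at -0.95 ± 0.14 and anillin (Anln) at -0.92 ± 0.16. Both probes of Aurkb lay in the last 64 rows. Of 30 DNA replication genes, 23 lay below 0 and 0 reached 2-fold, with a median of -0.32 at percentile 0. Cdc45, part of the replicative helicase, was at -0.86 ± 0.14, the ribonucleotide reductase subunits Rrm2 and Rrm1 at -0.81 ± 0.20 and -0.64 ± 0.20, and the clamp loader subunit Rfc3 at -0.61 ± 0.14. Rfc5 was at 0.16 ± 0.12 and Gins3 at 0.09 ± 0.20. Replication histones had a median of -0.50 at percentile 0, with 44 of 51 measured genes below 0. H3c11 was at -1.02 ± 0.20, H1f5 at -0.97 ± 0.20, H1f4 at -0.92 ± 0.20 and H3c13 at -0.90 ± 0.20, while H2ac18 was at 0.57 ± 0.20 and H2ac8 at 0.37 ± 0.21. H1f5, H3c13 and H2ac18 were measured in the last 64 rows alone, and H3c11 fell short of 2-fold with normexp.

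Members of the G1 cyclin list went both ways, from -1.75 to 1.0, with a median of -0.04 at percentile 34.5, or -0.23 at percentile 2.89 without the last 64 rows. Cyclin E1 (Ccne1) was at -1.75 ± 0.20 and the transcription factor E2f2 at -1.46 ± 0.14. Chosen after their values were seen, Ccnd1, Ccnd2 and Ccnd3 were at 0.15 ± 0.20, 0.03 ± 0.12 and -0.05 ± 0.12. Cyclin E2 (Ccne2) was well above background on the control array alone, at least 5.77-fold higher there, at a spot in the last 64 rows. CDK inhibitors had a median of 0.16 (percentile 85.6), and of 0.32 (percentile 98.7) without the filter on dim probes. STAT5 target genes had a median of 0.02 at percentile 53.8, with 12 of 22 measured genes above 0. Onecut1 was the member past 2-fold (1.04 ± 0.18), and its probes gave 0.62 and 1.46. It fell short of 2-fold with normexp, with the brightest probe and with RefSeq probes alone. Also chosen after their values were seen, the kinase Pim1 was at -0.90 ± 0.21, Igf1 at -0.61 ± 0.15, Bcl2l1 at -0.39 ± 0.09, Socs2 at 0.56 ± 0.10 and Bcl2 at 0.55 ± 0.13.

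Interferon-stimulated genes were higher on the knockdown array. Of 26 measured, 24 lay above 0 and 9 were at least 2-fold higher, with a median of 0.82 (interval 0.45 to 1.06) against -0.17 to 0.21 for random lists, at percentile 100. The antiviral gene Ifit1 was at 2.72 ± 0.23, Xaf1 at 2.49 ± 0.28, the 2-5A synthetase Oas1a at 1.60 ± 0.23 and the RNA sensor Ddx58 at 1.42 ± 0.15. Mx1 was at -0.23 ± 0.15 and Oasl1 at -0.01 ± 0.14. The Xaf1 probe lay in the last 64 rows. Another Xaf1 probe, outside them, was well above background on the control array alone and differed by -0.76, and without the filter on dim probes Xaf1 and Psmb9 were under 2-fold. With normexp Oas1a fell short of 2-fold. Genes of MHC class I antigen presentation had a median of 0.39 at percentile 99.85, with 11 of 13 above 0. The immunoproteasome subunits Psmb8, Psmb9 and Psmb10 were at 1.34 ± 0.20, 1.32 ± 0.20 and 0.89 ± 0.20, and the peptide transporter Tap2 was at 0.53 ± 0.21. Nlrc5 was at -0.16 ± 0.19 and H2-Q4 at -0.11 ± 0.20. Microglia and immune cell markers had a median of 0.08 (percentile 68.2), with 1 of 12 measured members past 2-fold, Tmem119 (1.80 ± 0.24).

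**Figure D2:**
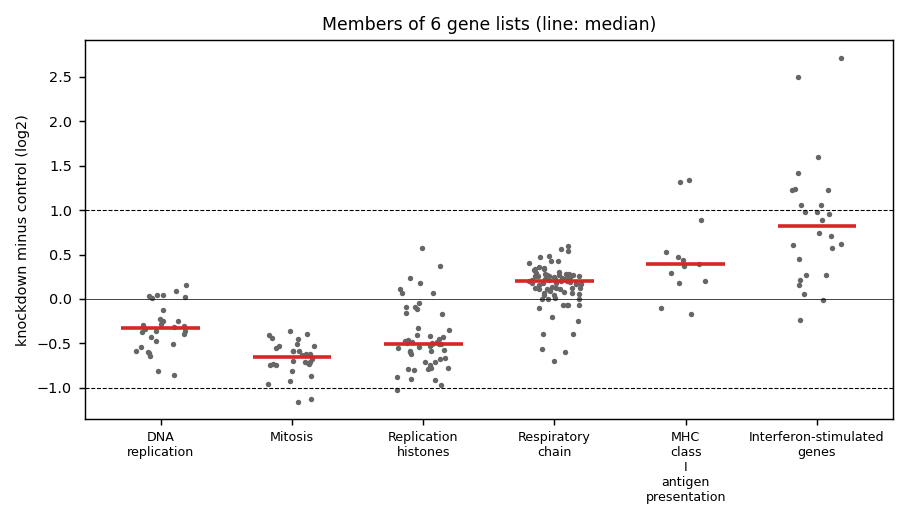
Knockdown minus control log2 difference of each measured member of 6 gene lists, with the list's median as a red line and dashed lines at 2-fold. All 30 mitosis genes lie below 0, and 24 of 26 interferon-stimulated genes lie above it.

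Respiratory chain genes had a small shift upward, with a median of 0.20 at percentile 100 and 66 of 81 measured genes above 0, of which 0 reached 2-fold. Ndufs3 was at 0.59 ± 0.17 and Yjefn3 (in the list through the file's symbol) at 0.57 ± 0.20. Cox7a1 was at 0.55 ± 0.20 and Ndufc1 at 0.48 ± 0.20. Against these, Atp5d was at -0.60 ± 0.20 and Ndufv2 at -0.70 ± 0.15, the latter from probes at -0.15 and -1.24. The p53 targets had a median of 0.19 at percentile 97.6, with 4 of 25 at least 2-fold higher and 1 lower. Of the 8 alternatives that move percentiles, this list stood apart under 1, that without the filter on dim probes. Ddit4l was at 1.99 ± 0.21, Dcxr at 1.36 ± 0.10, Sesn1 at 1.28 ± 0.20 and Btg2 at 1.08 ± 0.14, while Plk3 was at -1.02 ± 0.20 and Gadd45a at -0.70 ± 0.20. The 4 Dcxr probes ranged from 0.19 to 1.92. Btg2 fell short of 2-fold with the brightest probe and Plk3 with normexp. Olfactory receptor genes, of which 91 of 1087 were measured, had a median of -0.12 at percentile 0.27, and stood on the low side of random lists in the main setting and under 7 of those 8 alternatives, not among brighter probes. Olfr331 (-2.71 ± 0.26), Olfr609 (-0.90 ± 0.25) and Olfr616 (1.40 ± 0.25) lay in the last 64 rows, and Olfr1026 (-0.83 ± 0.30), Olfr482 (-0.72 ± 0.30) and Olfr124 (0.66 ± 0.29) did not. Olfr616 fell short of 2-fold with normexp. The olfactory receptor list was set as a check of the detection flag, in a family with little expression outside olfactory tissue. That it stood apart itself limits what percentiles of lists of dim genes can show.

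**Figure D3:**
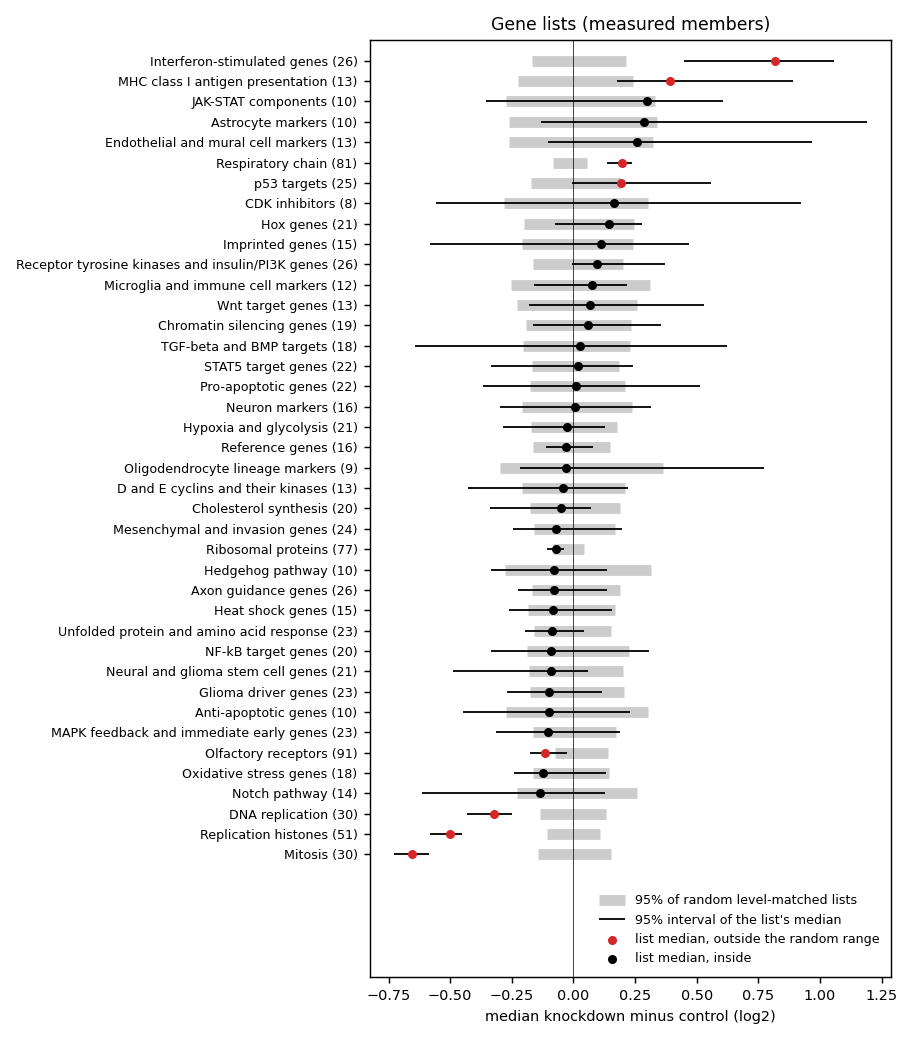
Median knockdown minus control log2 difference of each of 40 gene lists (points), with its 95% interval over genes (black lines) and the range of 95% of random level-matched lists (grey). The 8 lists in red lie outside that range, from mitosis at -0.65 to interferon-stimulated genes at 0.82.

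Cell identity lists lay within the limits in the main setting. Neural and glioma stem cell genes had a median of -0.09 (percentile 14.4), with the adhesion molecule L1cam at -1.39 ± 0.31 and Id3 at -1.06 ± 0.21. Astrocyte markers had a median of 0.29 (percentile 95.1), with the sodium pump subunit Atp1b2 at 1.88 ± 0.20 and the aldolase Aldoc at 1.19 ± 0.07. The astrocyte gene S100b was well above background on the knockdown array alone, at least 10.1-fold higher, and Gfap, the filament protein of astrocytes, on the control array alone, at least 1.53-fold higher. With normexp the astrocyte median was 0.23 at percentile 98.0. Over the 10 alternatives the astrocyte median ranged from 0.10 to 0.40 and its percentile from 68.65 to 98.88. Endothelial and mural cell markers had a median of 0.26 (percentile 94.3), with Pdgfrb at 2.19 ± 0.33 and Col1a2 at 1.63 ± 0.19. A further Col1a2 probe, well above background on the control array alone, went the other way (-2.48). Without the last 64 rows this median was 0.46 at percentile 99.3. Lum, of the same list, was well above background on the control array alone, at least 5.92-fold higher, at a spot among others of that kind near the array's side. Oligodendrocyte lineage markers were at -0.03 (percentile 37.4) and neuron markers at 0.01 (percentile 47.7). The lineage factor Olig2 was well above background on the knockdown array alone, at least 4.40-fold higher, at a spot in the last 64 rows. With normexp, L1cam, Id3, Tmem119 and Pdgfrb fell short of 2-fold, as did Col1a2 without the filter on dim probes.

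Among the signalling lists, the NF-kB targets (median -0.09, percentile 14.1) went both ways, with Ptgs2 at -1.41 ± 0.20 and Cxcl1 at -1.20 ± 0.21 against the chemokines Ccl5 at 1.71 ± 0.20 and Ccl7 at 1.17 ± 0.30. TGF-beta and BMP targets (0.03, percentile 56.2) held Id2 at -1.96 ± 0.15, Skil at -1.09 ± 0.14 and Tgfb2 at 1.01 ± 0.14. Without the last 64 rows its median was 0.33 at percentile 99.35. Over the 10 alternatives its median ranged from -0.04 to 0.33 and its percentile from 22.59 to 99.35. The Hedgehog pathway (-0.08, percentile 26.6) held Hhip, an inhibitor of that pathway, at -1.77 ± 0.14, measured in the last 64 rows alone. Receptor tyrosine kinases with insulin and PI3K genes (0.10, percentile 80.2) held Pdgfrb, given above. Wnt targets (0.07, percentile 68.2) held Ascl2 at 1.56 ± 0.23, also from the last 64 rows. The Notch pathway was at -0.13 (percentile 11.7) and MAPK feedback and immediate early genes at -0.10 (percentile 9.22). With normexp, Cxcl1, Ccl7, Skil, Tgfb2 and Ascl2 fell short of 2-fold, as did Tgfb2 with median scaling and with the brightest probe and Ascl2 without the filter on dim probes.

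Anti-apoptotic genes had a median of -0.10 (percentile 21.3) and pro-apoptotic genes of 0.01 (percentile 49.2), with Bik at -2.05 ± 0.21 and Bmf at 1.50 ± 0.17. The 2 Bmf probes were at 0.77 and 2.24. Mesenchymal and invasion genes were at -0.07 (percentile 19.9), with Thbs1 at 1.03 ± 0.15. Hypoxia and glycolysis genes were at -0.03 (percentile 38.5), with the oxidoreductase Ero1a at -1.47 ± 0.20. Oxidative stress genes were at -0.12 (percentile 6.99), with the heme oxygenase Hmox1 at -1.13 ± 0.20. Chromatin silencing genes were at 0.06 (percentile 65.2), and at 0.27 (percentile 98.2) among brighter probes. Imprinted genes were at 0.11 (percentile 79.1), with Peg10 at 1.86 ± 0.15 and Peg3 at -1.13 ± 0.13. Axon guidance genes were at -0.08 (percentile 16.7), with Efna5 at 1.09 ± 0.14. Peg3 fell short of 2-fold among brighter probes and with the brightest probe, and Thbs1 and Peg3 with normexp. Peg3 also did with RefSeq probes alone and without the last 64 rows.

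Medians of the other lists lay within the random range: the unfolded protein response at -0.09 (percentile 15.2), cholesterol synthesis at -0.05 (percentile 28.7), heat shock genes at -0.08 (percentile 21.0), glioma drivers at -0.10 (percentile 11.3) and Hox genes at 0.14 (percentile 87.1). Reference genes were at -0.03 (percentile 42.4) and ribosomal protein genes at -0.07 (percentile 6.20), with 57 of 77 of the latter below 0.

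Well above background on the control array alone were 624 genes, of which 134 had a bound of at least 2-fold. On the knockdown array alone there were 503, of which 200 had such a bound. With clone and predicted-gene names left out, the largest bounds on the control array were those of Krt71 (at least 30.0-fold), Ddo (28.3), Il17a (27.9), Pm20d2 (26.7) and Nell1 (25.2). On the knockdown array, with such names left out, they were those of Tram1l1 (at least 31.9-fold), Smco3 (25.3), Cdr1os (22.9), Sox14 (21.4) and Krt33b (21.0). The probes that gave these bounds, that of Krt33b apart, lay in the last 64 of 384 rows. Of 114 gene probes with a bound of at least 8-fold, 106 (93.0%) lay in those rows, which hold 16.6% of probes. A recount without those rows gave 151 genes with a bound of at least 2-fold, 43 on the control array and 108 on the knockdown array, of which 139 were among the 334 counted over all rows.

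**Figure D4:**
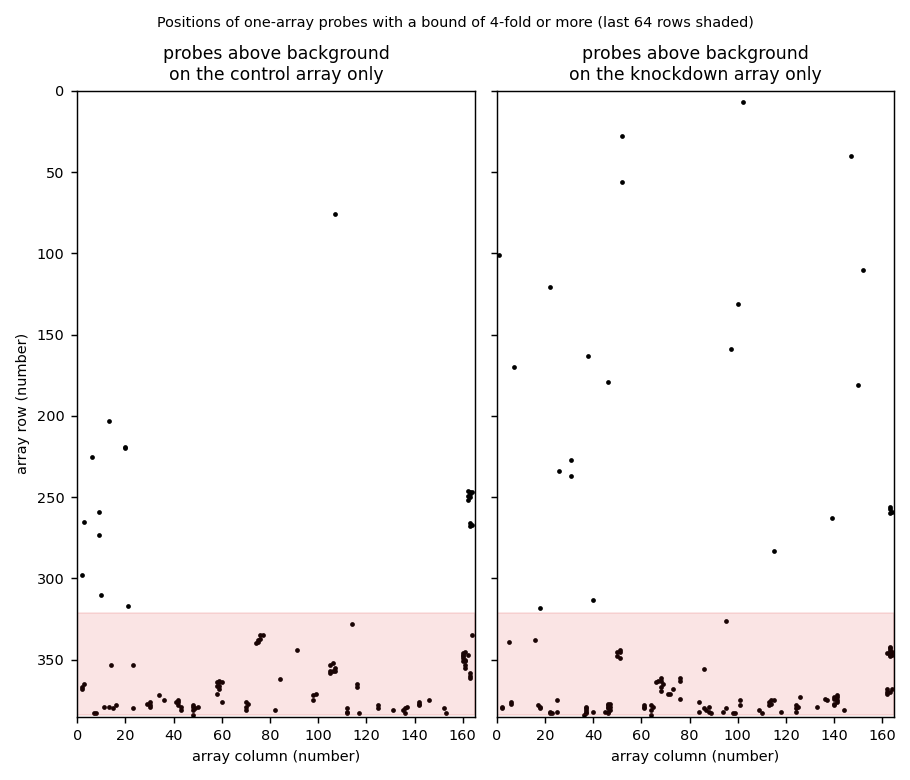
Array row and column (numbers) of gene probes well above background on 1 array only with a bound of 4-fold or more, on the control array (left) and the knockdown array (right), with the last 64 rows shaded. Of 252 such probes, 207 lie in the shaded rows.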

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

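Among the tests below, those of immune cell RNA, of signal level, of the position of gene probes and of control spots counted over places were chosen after the result was seen; the others were set before it. The choice of the last 64 rows was itself made after signals on 1 array were seen to gather there. How to read the test of further probes was changed after its value was seen.

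Probes without a gene name stood outside the comparisons by gene. Of 10429 such probes 4 were lost to outlier flags. Of the remaining 10425, 4497 were well above background on both arrays, and 75 of them were at least 2-fold higher and 84 at least 2-fold lower on the knockdown array. Outside the last 64 rows these counts were 55 and 57.

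The first pattern was the rise of interferon-stimulated genes, for which RNA from immune cells would have brought immune markers along, but their list had a median of 0.0765 (interval -0.16 to 0.22), with 8 of 12 above 0. Tmem119 was at 1.80, against C1qb at -0.18, Laptm5 at -0.16 and Fcer1g at 0.09 (the last 3 chosen after their values were seen). A bias of dim probes would have moved random lists of the same levels, yet the interferon list lay at percentile 100. The list was picked by that percentile, so this test could not have come out otherwise and decides nothing. Among brighter probes the percentile was 99.99. The list's median of 0.82 was 0.82 without the last 64 rows and 0.62 among brighter probes and without the filter on dim probes. It was 0.55 with normexp and 0.53 with normexp and quantile scaling, so its size depended on how dim probes were treated. Over the 10 alternatives the list's median ranged from 0.53 to 0.93. A set of 54 further measured interferon-stimulated genes, listed before their median was computed, had a median of 0.55 (interval 0.34 to 0.74) against -0.11 to 0.14 for random lists, so the rise was not limited to the listed genes. A response to the lower Stat5b, or to the hairpin or the virus, may stand behind it; neither was tested, and 1 array per hairpin leaves both open.

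The second pattern was the fall of mitosis, DNA replication and histone genes. A bias tied to signal level would have moved matched random lists too, and the mitosis list lay at percentile 0 of them. The list was picked by that percentile, so this test could not have come out otherwise and decides nothing. Without the last 64 rows the list's median was -0.62. A set of 46 further mitosis genes, listed before their median was computed, had a median of -0.61 (interval -0.80 to -0.51), with 43 of them below 0. Random lists matched to that set on level lay between -0.12 and 0.13. The share of dividing cells and the density and growth phase of the cultures were not tested and stay open.

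The third pattern was signal on 1 array only. Defects near one end of the arrays may account for most large bounds: 93.0% of gene probes with a bound of at least 8-fold lay in the last 64 rows. Negative control spots, which match no transcript, were well above background on an array at 6 of 50 places in those rows and at 1 of 258 elsewhere (Fisher's exact test over places, one-sided, p = 8.62e-05; counting each place once per array, p = 9.78e-05). If the knockdown had switched these genes on or off, their further probes would have moved with them. The median of 44 such probes was 0.11, which the rule set beforehand would have counted against such switching. That rule was set aside after the value was seen, because 40 of the probes were not well above background on the array in question. The question thus stays open.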

How the results depend on the processing

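Alternatives with normexp, without the last 64 rows and with RefSeq probes alone were chosen after seeing the data. Stat5b stayed within its scanner error of -2.0 under 9 of 10 alternatives. Those 9 rest on the same 1 probe, so they do not set the value against another probe. Without the filter on dim probes it was -1.49, because its dim probe then entered the mean. The 600 higher and 394 lower genes became 191 and 167 with normexp, 188 and 166 with normexp and quantile scaling, 211 and 229 among brighter probes, and 1282 and 1000 without the filter. Without the last 64 rows they became 525 and 321. Of the counted genes 599 were not measured among brighter probes, and 163 were not measured without those rows. Of those counted with normexp, 189 and 166 were also counted by the main setting. The 334 genes with a bound of at least 2-fold became 71 with normexp, 71 with normexp and quantile scaling, and 151 without the last 64 rows. Normexp added an offset of 50, above the median processed signal of 43.2 on the control array and 44.2 on the knockdown array. Such an offset damps the log2 differences of dim probes by construction. How much of the drop with normexp it accounts for was not tested.

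Of the list medians under alternatives, 398 stayed within the list's interval and 2 did not. Ribosomal protein genes moved to -0.0254 with normexp and quantile scaling, for which the cause was not tested. Olfactory receptor genes had a median of 0.1129 without the filter, where random lists lay between 0.113 and 0.115. The change of sign is thus an offset shared by dim probes, and the list lay only just below the random range there. Median scaling and the authors' table shift all genes alike and leave percentiles as they were. Under all 8 other alternatives mitosis, DNA replication, histone, respiratory chain, interferon-stimulated and MHC class I genes stood apart, under 7 olfactory receptors and under 1 p53 targets. Astrocyte markers stood apart under 3 and endothelial and mural cell markers under 2. JAK-STAT components, TGF-beta and BMP targets, CDK inhibitors and chromatin silencing genes each stood apart under 1.

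Of 67 named genes past 2-fold besides Stat5b, 44 stayed past it under each alternative that measured them, 23 did not, and 0 values turned sign. Measured in the last 64 rows alone were 8 of them. Dim probes limit the measurement, since 59.5% and 58.6% of probes were well above background. No paired analysis was possible because each group has 1 array, and for the same reason no array was left out and no other split of the samples exists. The planned normexp on the mean signal was not run.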

Other observations

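Further genes of both shifted groups moved with the lists. Among the further interferon-stimulated genes, chosen after their values were seen, the ubiquitin-like activating enzyme Uba7 was at 2.92 ± 0.23, the GTPases Tgtp2 and Ifi47 at 2.57 ± 0.30 and 2.04 ± 0.23, and 11 of 54 were at least 2-fold higher with 0 lower. Mlkl was at -0.44 ± 0.20. Among the further mitosis genes 6 of 46 were at least 2-fold lower, among them the condensin subunit Ncapg2 (-1.27 ± 0.20) and the cohesin protectors Sgo1 (-1.11 ± 0.14) and Sgo2a (-1.11 ± 0.21). Cenph was at 0.20 ± 0.22. These genes were also chosen after their values were seen.

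Outside the last 64 rows, with clone and predicted-gene names left out, large bounds on the control array were those of Mageb5 (at least 20.9-fold), Runx1t1 (14.5), Abcd2 (6.61) and Lum (5.91). Their probes lay together at rows 247, 246, 249 and 252 and columns 163, 162, 162 and 162, beside other spots bright on the control array alone. On the knockdown array they were those of Krt33b (at least 21.0-fold), the Notch target Hey2 (12.5), S100b (10.1), Clec4b1 (7.22) and Lrguk (6.21). Hey2 and Clec4b1 lay side by side at rows 257 and 256 of column 163, near further spots bright on the knockdown array alone. Of 45 gene probes with a bound of at least 4-fold outside the last 64 rows, 14 lay in the last 5 columns, which hold 3.0% of probes there. These names were chosen after the rows were left out.

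Of the genes measured by several probes, 2 had probes that differed 2-fold in opposite directions, Nrp2 (-2.75 and 1.0) and Wfdc3 (-3.00 and 1.17). Each of these Nrp2 probes and the lower Wfdc3 probe lay in the last 64 rows. Log2 differences of neighbouring genes along the chromosomes, histones left out, correlated at 0.0636 across 15589 genes, above the highest value of 0.0287 in 10000 shuffled orders. Other families of related neighbouring genes were kept, and shuffling separates their members too. What lies behind the correlation was not tested.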
